A study of Arabidopsis thaliana with 12 samples.

How the data were processed

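Transcript levels were measured on 12 expression arrays of Arabidopsis thaliana RNA, 6 from wild type (WT) and 6 from prpl11. The labels gave the genotype and a replicate number from 1 to 6 for each array and named neither tissue, growth conditions, label nor array type. Nothing in the labels says that replicates came from separate plants or cultures, so p-values measure only the spread between these arrays, which may be technical.

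The deposited table held 1 intensity per probe and array for 3439 probes. The values were on a linear scale with no negative entries, and the authors' scaling between arrays is read from the values themselves, since array sums lay between 3597 and 3678. The background correction, the reference of the scale and the scanner software are not given in the sources used here. The highest deposited intensity lay within 1e-6 of 100 for 5 values, all on prpl11 arrays. Between 138 and 148 probes per array were listed at 0. No measure of background was used here, and the number of arrays limits the precision.

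Values at or below 0 were set to the 1st percentile of positive values, an intensity of 0.0583, and log2 was taken. Positive values below that percentile were left as they were, so a probe listed at 0 can sit above a very dim one on the log2 scale. The medians of the 12 arrays ranged from -0.79 to -0.68 on the log2 scale. Their range of 0.11 was above the limit of 0.1 set before the data were examined, and the arrays were quantile normalized. The 108 probes at 0 on all 12 arrays were left out of the tests, a step that was not part of the plan, and 3331 probes were tested. Another 48 probes were at 0 on some arrays and were kept.

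The gene table that accompanied the probes listed 1 gene for 692 probes, several for 870 and none for 1877. Genes were named only from probes with 1 gene, 665 of which were tested, and symbols were taken through gene identifiers from the TAIR10.1 gene table, in which 2 of the 692 were not found. A probe with no listed gene is unnamed here and is not a probe without a gene. The files name no genome build, so no coordinates are given and the gene table was used only for names and gene order.

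Differences are prpl11 minus WT on the log2 scale from limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no block, 10 residual and 2.92 prior degrees of freedom), with Benjamini-Hochberg adjusted p-values over all 3331 probes and a threshold of 0.05. Standard errors are the moderated ones of that fit. Mean intensities and their SDs are given as deposited, before normalization, while log2 changes come from the normalized values. Figures were drawn with matplotlib 3.10.9. On simulated values with the spread of these 3331 probes and 200 changed probes, the fit recovered 53.1% of changes of 0.3, 89.3% of 0.6 and 97.0% of 1 on the log2 scale with independent arrays, and 4.77% of its calls were false. With arrays that shared 3 sets the shares were 56.9%, 89.7% and 96.8%, and 1.22% of calls were false. Simulated set effects were equal in both genotypes, and noise was drawn independently for each probe. The false shares therefore leave out set effects that differ between genotypes and noise shared between probes.

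Replicate numbers are shared by the genotypes. Deviations from the genotype means correlated between WT and prpl11 arrays of the same number at 0.288 to 0.514 over probes, above 0.1 in all 6 pairs, and among the arrays of the other genotype each of the 12 arrays correlated best with that of its own number. Within its own genotype, prpl11 replicate 1 correlated more strongly with replicate 2 (0.342) and prpl11 replicate 4 with replicate 3 (0.386). By the rule fixed for this check the numbers pair the arrays; the pairing comes from the data, not from the labels. Neighbouring numbers (1 and 2, 3 and 4, 5 and 6) also went together. Within a genotype their log2 values differed by a median of 0.09, against 0.17 for other arrays of that genotype. These 3 groups of 4 arrays are called sets below. The limma duplicate correlation within genotype and set was 0.673, and 0.077 after a set block. The p-values of the fit without a block treat the 6 arrays of a genotype as independent. The fit with the replicate number as a block is given beside the probe counts and the calls of named genes and lists that it changes. Counts of called list members are given without the block.

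Before the data were examined, 18 gene lists with 327 members were fixed for plastid functions and for other tissues. Only 16 of these genes had a probe of their own, and 2 of the lists, photosystem II subunits and plastid ribosomal proteins, had the 3 tested members that a test required. A list of cytosolic ribosomal proteins depended on gene descriptions and was not formed. After the gene table and some mean intensities had been seen, and before any fold change, 7 further lists were added. Lists were tested with camera at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the 9 lists.

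Genes were named by a rule fixed beforehand: the 6 largest increases and the 6 largest decreases among genes past the threshold in which at least 5 of the 6 values of one genotype lay beyond the other genotype's median, then from each list the 2 called members with the largest change or, where none was called, the member with the lowest p. The rule was also applied to the added lists. Alternatives fixed beforehand changed the pairing, the scaling, the treatment of low values, the variance model, the threshold and the set test, and left out each array in turn. Others were added after seeing the data, and layout tests used a grid of probe IDs that is inferred and not given in the sources used here. With a random block, array weights or a trended and robust variance, lists were tested on the moderated statistics with the same preset correlation.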

Results

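The series compared expression between WT and prpl11, a line named after PRPL11, which encodes protein L11 of the large subunit of the plastid ribosome. Relative transcript intensities were measured for 3439 probes on 6 WT and 6 prpl11 arrays, with 1 value per probe and array. Array sums lay between 3597 and 3678 and array medians between 0.567 and 0.611, in the arbitrary units of the deposited intensities. PRPL11 itself (AT1G32990) was not among the genes with a probe of their own and its level was not analysed here, so the genotype labels could not be checked against it.

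Which genes differed between prpl11 and WT was asked with all 12 arrays. In prpl11, transcripts of PSAN, a nuclear-encoded subunit of photosystem I, and of CYN, the enzyme cyanase, were about 1.5-fold higher than in WT. Those of PRK, the phosphoribulokinase of the Calvin cycle, were lower. The calls of PSAN and CYN held in the 29 alternative fits run, while that of PRK was lost in 2 of 29. Changes were small: 184 of 3331 probes (5.52%) passed the threshold in limma, 82 higher and 102 lower in prpl11, and the median absolute change among them was 0.37 on the log2 scale. Of these, 37 probes carried 1 listed gene, 15 higher and 22 lower, while 32 carried several and 115 none. At least a 2-fold change was reached by 2 probes upward and 4 downward, none of which had a single listed gene. The sign was the same in all 6 replicate pairs for 181 of the 184 probes. Calling probes on these same arrays favours that outcome, so it adds no support, here or for single called genes below.

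With the replicate number as a block, which takes out what same-numbered arrays share, 649 probes passed, 343 higher and 306 lower. Of these, 135 carried 1 listed gene, against 37 without the block. Among the 649 were 183 of the 184, with the same sign, which a block cannot change in this balanced design. With neighbouring replicate numbers averaged to 3 values per genotype, 23 probes passed, 7 higher and 16 lower, and with the 3 sets as a block on these averages 138 passed, 48 higher and 90 lower, of which 109 were among the 184. Higher calls made up 44.6% of calls after quantile normalization, 32.6% after median centring, 31.8% after centring on genes outside the lists and 28.2% without normalization, so the balance of increases and decreases depended on the scaling.

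The largest increases among genes were in CYN (AT3G23490), PSAN (AT5G64040), AT3G09850, AT5G19750, AT3G23940 and AT4G05070. CYN rose from 3.09 ± 0.17 to 4.51 ± 0.55 (SD, n = 6 arrays each), a log2 change of 0.64 ± 0.06 (SE, limma adjusted p = 4.61e-05). PSAN rose from 4.64 ± 0.094 to 6.80 ± 0.96 (SD, n = 6), a log2 change of 0.62 ± 0.06 (SE, limma adjusted p = 3.84e-05). Both were higher in prpl11 in 6 of 6 replicate pairs and stayed past the threshold in the 29 alternative fits run. AT3G23940, a dihydroxyacid dehydratase of branched-chain amino acid synthesis, rose by 0.38 ± 0.05 (SE), with AT5G19750 at 0.38 ± 0.06 and AT4G05070 at 0.37 ± 0.07. AT3G09850 was among the brightest probes, with 35.6 ± 1.7 in WT and 49.2 ± 5.3 in prpl11 (SD, n = 6). Its change of 0.43 ± 0.09 (SE) ranged from 0.22 to 0.81 between the 3 sets. Averaging to 3 values per genotype ended the calls of these last 4 genes, with limma adjusted p between 0.136 and 0.378, the lowest over all alternatives being 2.35e-06 for AT3G23940. AT3G09850 and AT4G05070 also lost their calls on set averages with the sets as a block. AT5G19750 and AT4G05070 lost theirs with genotype within set as a random block alone.

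The largest decreases were in AT5G38360, AT3G09080, AT4G31470, AT4G29890, LpxA (AT4G29540) and AT1G21660. AT4G31470 fell from 2.82 ± 0.25 to 1.56 ± 0.17 (SD, n = 6), a log2 change of -0.76 ± 0.08 (SE, limma adjusted p = 4.93e-05), and AT1G21660 from 2.22 ± 0.10 to 1.403 ± 0.098 (SD, n = 6), a log2 change of -0.59 ± 0.06 (SE, limma adjusted p = 2.72e-05). AT3G09080 changed by -0.76 ± 0.11, AT4G29890 by -0.61 ± 0.14 and LpxA, an acyltransferase of the lipid A type pathway, by -0.61 ± 0.11 on the log2 scale (SE). AT5G38360 had a log2 change of -0.89 ± 0.20 (SE) at very low intensity, 0.0796 ± 0.014 in WT and 0.041 ± 0.0076 in prpl11 (SD, n = 6), the latter below the 0.0583 given to probes listed at 0, so the size of its change is uncertain. With a pseudocount of 0.236, the 10th percentile of positive intensities, its change was -0.15 with a limma adjusted p of 0.0627, within a range over its alternatives of 0.000667 to 0.388, and it also lost its call with trended and robust variance (0.0520) and with genotype within set as a random block (0.388). LpxA, AT4G29890 and AT4G31470 lay within 300 places of each other in gene order on chromosome 4, in a stretch where 5 of 10 probes were called lower. On a grid of probe IDs inferred from the data, AT4G31470, AT1G21660, LpxA and AT3G09080 lay beside other called decreases, with 6, 4, 3 and 2 of them at neighbouring positions. Averaging to 3 values per genotype ended the calls of AT5G38360, AT3G09080, AT4G29890 and LpxA (limma adjusted p between 0.140 and 0.394). AT4G29890 also lost its call with genotype within set as a random block alone. AT4G31470 and AT1G21660 stayed past the threshold in the 28 alternative fits run for them. The fit that left out probes with a called neighbour did not include these genes.

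**Figure D1:**
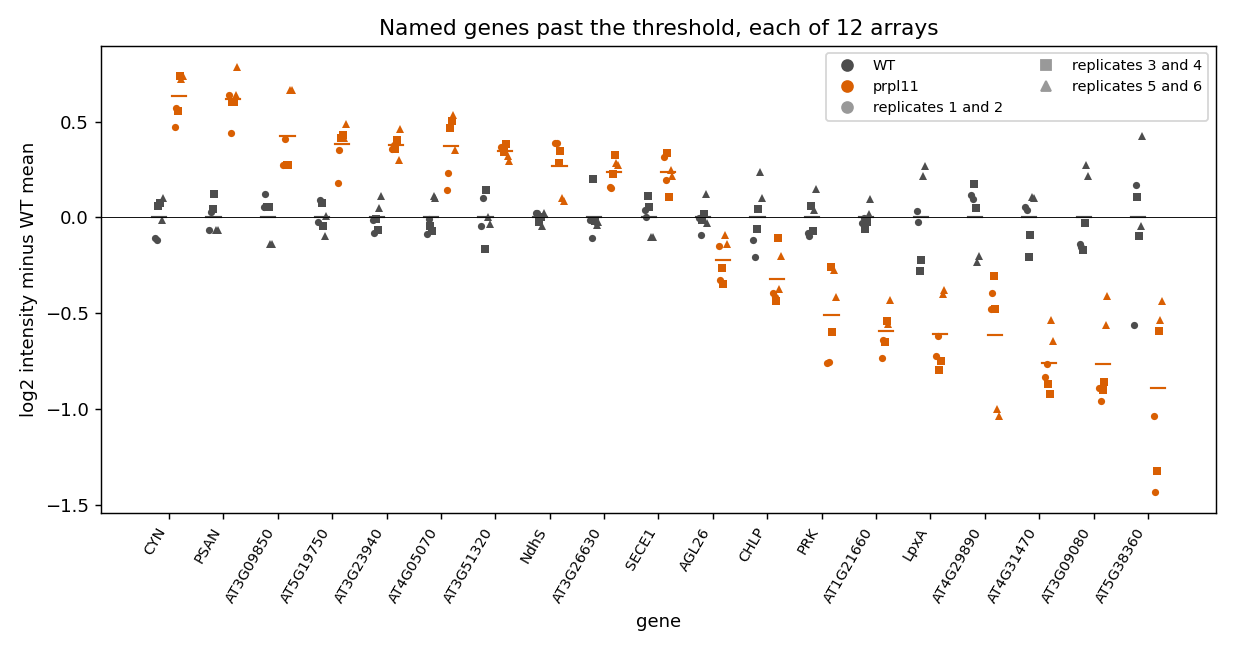
Each point is the normalized log2 intensity of 1 array minus the WT mean of that gene, for the 19 named genes past the threshold, in WT (grey) and prpl11 (orange), with short lines at the 6-array means and marker shapes for the 3 sets of replicate numbers. CYN and PSAN sit highest in prpl11, at means of 0.64 and 0.62, and AT5G38360 lowest at -0.89.

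**Figure D2:**
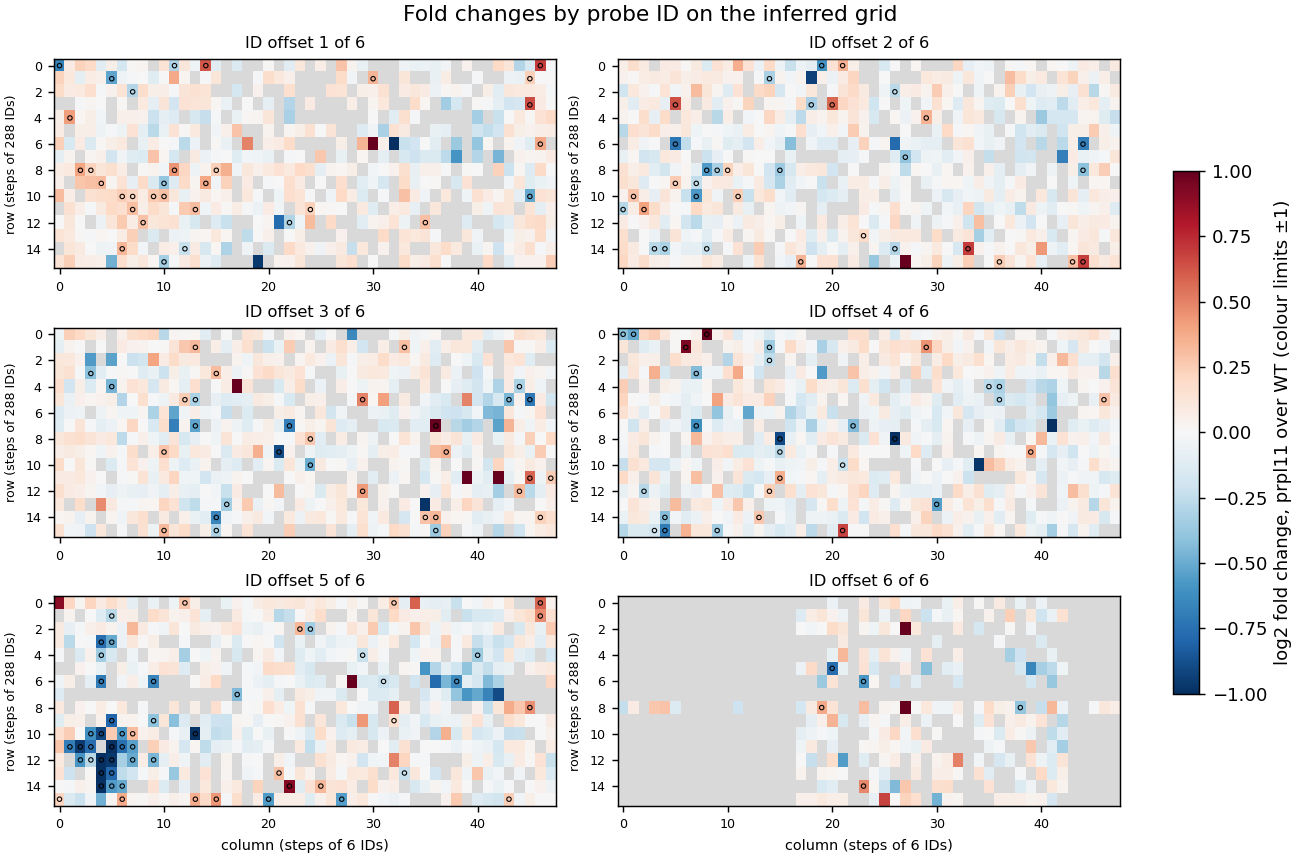
Log2 fold changes of prpl11 over WT (colour, limits ±1) are laid out by probe ID on the inferred grid, 1 panel for each of the 6 ID offsets, with 48 columns in steps of 6 IDs and 16 rows, both counted from 0; circles mark probes past the threshold and grey marks places with no value drawn. Of the 102 called decreases, 47 had another called decrease beside them, 23 of these in offset 5.

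Among genes of photosynthesis, PSAN rose and the Calvin cycle gene PRK fell, and no shift of the group passed the test (camera adjusted p = 0.933). Of 7 measured members of the pooled photosynthesis lists, PSAN rose, PRK fell and 5 passed no threshold, and the same 2 passed when adjusted over the list alone. PRK fell from 0.822 ± 0.050 to 0.579 ± 0.072 (SD, n = 6), a log2 change of -0.51 ± 0.10 (SE, limma adjusted p = 0.00515), lower in 6 of 6 replicate pairs. Averaging to 3 values per genotype gave a limma adjusted p of 0.205 for PRK, the highest of its alternatives. PRK also lost its call with genotype within set as a random block alone. The other Calvin cycle gene measured, SBPASE, had a log2 change of -0.13 and did not pass. None of the 3 photosystem II subunits passed, over all probes or adjusted over the list alone. PSB27 had 0.15, PSBW -0.06 and PSBY -0.19 on the log2 scale. LHB1B2, which encodes a chlorophyll a/b-binding protein of the LHCB1 family, had 0.19 ± 0.09 (SE, limma adjusted p = 0.332), and copies of that family may share its probe. With the replicate block, PSB27 (adjusted p = 0.047) and LHB1B2 (adjusted p = 0.0473) passed in limma, but on set averages with the sets as a block neither did (0.241 and 0.103); over all alternatives their adjusted p ran from 0.0373 to 0.999 and from 0.0253 to 0.999.

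For transcripts of the plastid's own ribosome no shift of the group passed the test. None of the 5 measured genes passed over all probes, and PRPS6 alone passed when adjusted over the list alone. PRPS6, a protein of the small plastid ribosomal subunit, went from 0.278 ± 0.024 to 0.347 ± 0.033 (SD, n = 6), a log2 change of 0.33 ± 0.10 (SE, limma adjusted p = 0.09), higher in 6 of 6 pairs. The replicate block brought PRPS6 past the threshold (limma adjusted p = 0.00487), as did median centring (0.0409) and no normalization (0.0271), with 0.00124 to 0.745 over all alternatives. On set averages with the sets as a block PRPS6 did not pass (limma adjusted p = 0.0668). PRPL34, PRPL5, PRPL17 and PRPS10 had log2 changes of 0.08, 0.07, 0.06 and -0.02. The median of the list was 0.07 and its camera adjusted p was 0.849.

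Among genes for assembly of the photosynthetic complexes, the plastid NDH complex and plastid biogenesis, 2 of 18 rose, none fell and 16 did not pass, with the same 2 when adjusted over the list alone. NdhS, a subunit of the plastid NADH dehydrogenase-like complex, rose by 0.27 ± 0.06 and SECE1, a subunit of the plastid Sec translocase, by 0.24 ± 0.06 (SE). Of 24 organellar pentatricopeptide repeat (PPR) and mTERF proteins, 2 rose, none fell and 22 did not pass, against 3 that rose when adjusted over the list alone. Both were PPR genes, AT3G51320 at 0.35 ± 0.06 and AT3G26630 at 0.24 ± 0.06 (SE). Over the settings run their changes ranged from 0.16 to 0.37 and from 0.14 to 0.28. AT3G51320 was dim, with a mean intensity of 0.19 in WT. AT1G79220, which passed over the list alone, had 0.24 ± 0.06 (SE) and a limma adjusted p of 0.0511 over all probes. The list counts here come from the fit without the replicate block and are not given with it. Among all probes with a single listed gene, that fit called 37, the block 135 and averaging neighbouring numbers without a set block 4. How many members pass may therefore depend on the treatment of the pairing. The median of the PPR and mTERF list was 0.00 and turned to -0.018 with median centring, -0.019 with centring on genes outside the lists and -0.029 without normalization. CRR21, a member of both lists at -0.14, lay in a region of the grid where the 79 probes had a median of -0.20. Among 5 tetrapyrrole and carotenoid enzymes only CHLP, the geranylgeranyl reductase that supplies the side chain of chlorophyll, passed, over all probes and adjusted over the list alone. CHLP fell from 2.18 ± 0.26 to 1.65 ± 0.16 (SD, n = 6), a log2 change of -0.32 ± 0.08 (SE, limma adjusted p = 0.041). CHLM, of the same pathway, had 0.03.

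The calls of CHLP, NdhS, SECE1 and AT3G26630 lay close to the threshold. CHLP kept its call only without WT replicate 1, WT replicate 2, prpl11 replicate 4 or prpl11 replicate 6, and NdhS only without WT replicate 1, 2 or 6 or prpl11 replicate 5 or 6. SECE1 kept it without WT replicate 1, 3 or 4 or prpl11 replicate 2, 4 or 6, and AT3G26630 without WT replicate 3 or prpl11 replicate 1 or 2. The highest limma adjusted p among these single omissions was 0.0901 for CHLP, 0.0563 for NdhS, 0.0626 for SECE1 and 0.0708 for AT3G26630. CHLP also lost its call with array weights (limma adjusted p = 0.0510). NdhS and AT3G26630 lost theirs with median centring and with centring on genes outside the lists. Without normalization NdhS, AT3G26630, SECE1 and AT3G51320 all lost their calls. These were all the called increases of the biogenesis list and of the PPR and mTERF list. Averaging to 3 values per genotype gave the highest limma adjusted p of their alternatives, 0.468 for CHLP, 0.567 for NdhS, 0.530 for SECE1 and 0.538 for AT3G26630. All 4 calls were also lost on set averages with the sets as a block and with genotype within set as a random block alone. Without replicates 5 and 6 of both genotypes CHLP, SECE1 and AT3G26630 did not pass. AT3G51320 also lost its call with averaging (limma adjusted p = 0.148) and with genotype within set as a random block (0.157). CHLP, SECE1 and AT3G26630 each lay beside 1 other call of the same direction on the grid.

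**Figure D3:**
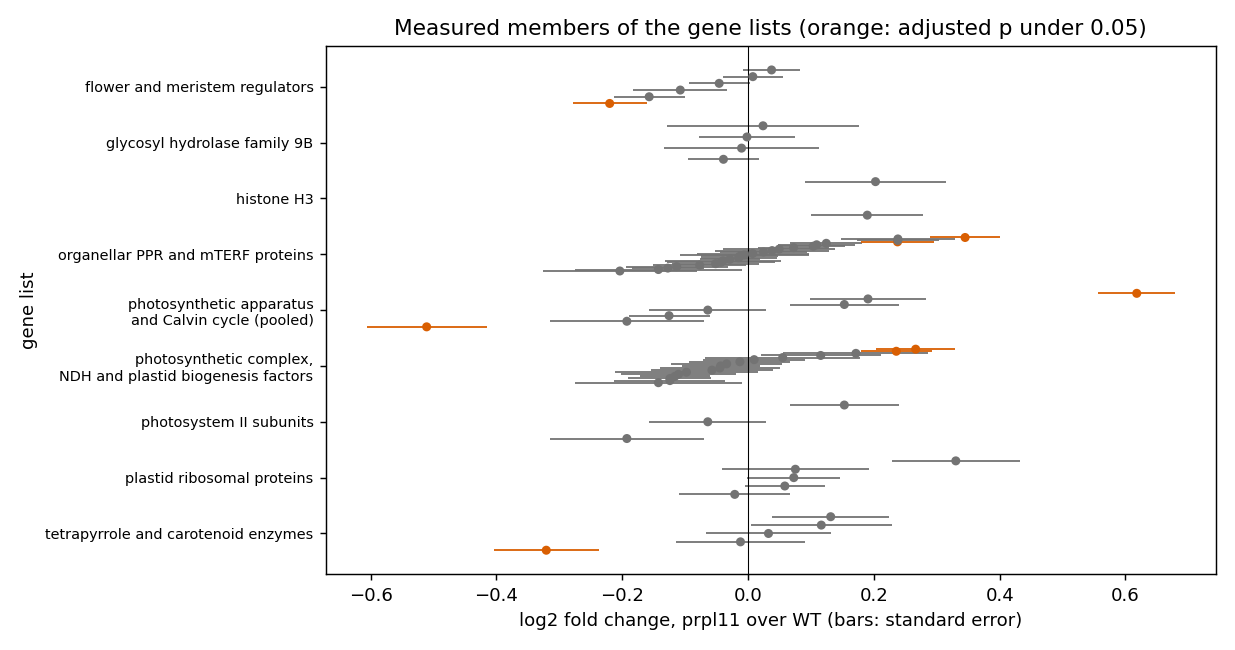
Points are log2 fold changes of prpl11 over WT for the measured members of the 9 tested lists, with bars of 1 standard error, orange where the adjusted p over all probes is under 0.05; members listed at 0 on any array are not drawn. PSAN at 0.62 and PRK at -0.51 lie at opposite ends of the pooled photosynthesis list, and its other 5 members lie within 0.2 of 0.

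The remaining lists held few measured genes. Among 6 flower and meristem regulators, AGL26, assigned to the list by its name, fell by 0.22 on the log2 scale (SE 0.06, limma adjusted p = 0.0466); AGL103, at -0.16, joined it when adjusted over the list alone. Among single omissions AGL26 kept its call only without prpl11 replicate 5, and without each of the other 11 arrays the limma adjusted p reached up to 0.0977. Median centring (0.0519) and averaging (0.615) also ended it. So did centring on genes outside the lists and set averages with the sets as a block. Genotype within set as a random block alone and leaving out probes with a called neighbour ended it too. None of 4 members of glycosyl hydrolase family 9B passed, GH9B12 having -0.04, and none of 3 histone H3 genes. AT1G13370, a histone H3 gene, had 0.19 ± 0.09 (SE) and passed with the replicate block (limma adjusted p = 0.0212, range over alternatives 0.0139 to 0.958), but not on set averages with the sets as a block (0.118). FATB, the only measured gene of plastid fatty acid synthesis, had -0.09 ± 0.06 (SE) and did not pass. No member of the list of markers of non-green tissue and senescence was analysed here, so differences in tissue composition were not examined.

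No list passed camera. The smallest adjusted p was 0.455, for the flower and meristem regulators, and 0.656 with an estimated correlation, and 0 of the 9 lists passed with either. At an unadjusted p under 0.05, camera passed 0 lists. The self-contained test fry passed 1 list, the flower and meristem regulators (adjusted p = 0.0168). The place of AGL26, the only called member, in that list is uncertain, and the test may rest on it. In the mixed form of fry, which asks for change in either direction, 3 lists passed, the PPR and mTERF proteins (adjusted p = 2.12e-06), the pooled photosynthesis list (1.36e-05) and the flower and meristem regulators (0.0115). These results may also rest on a few members and do not show change across a list. In the PPR and mTERF list 22 of 24 members were not called. In the pooled photosynthesis list 5 of 7 were not called, the others being PSAN and PRK. Fry was run without a block, so its p-values treat the arrays of a genotype as independent. The replicate block changed no list's call. For histone H3 the median was 0.19 and the mean -0.13, because AT5G65360, listed at 0 on 11 arrays, took a log2 value below the floor on the array where it was above 0. The pooled photosynthesis list had a median of -0.06 and a mean of 0.01, and the tetrapyrrole and carotenoid list a median of 0.03 and a mean of -0.01, with camera following the mean in both; for histone H3 it followed the median.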

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

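The search for arrays that stood apart was planned, and all tests of position on the array were chosen after the results had been seen. In the 50 groups of 6 arrays formed by the 25 named genes, 2 held an array far from the other 5, where chance gives about 2.5. WT replicate 3 stood above the other WT arrays for AT3G26630, with a log2 value of 1.51 against a mean of 1.27 and a gap of 0.692 of the whole range. Without that array the log2 change of AT3G26630 was 0.28 in place of 0.24. For GH9B12, prpl11 replicate 3 stood below the others, with -1.02 against -0.81 and a gap of 0.657 of the range.

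Called decreases lay close together when probe IDs were folded into a grid of 6 offsets, 48 columns and 16 rows, a layout inferred from the data: 47 of the 102 had another called decrease beside them, where 1000 random placements of the calls gave a mean of 17.3 and at most 33, and 27 of the 82 called increases lay beside another, against a mean of 11.4 and at most 28. The placements take this layout as given and do not allow for its having been inferred from the same data. A shared change of neighbouring genes stays open: log2 changes of 194 pairs of near genes not side by side on the grid correlated at 0.00789 (Spearman across genes, permutation SD 0.0716) against 0.163 for grid neighbours, but the pairs leave out clustered decreases. Uneven signal in a single set is open too, although the medians of the 47 in the 3 sets were -0.54, -0.55 and -0.54. All 102 called decreases were lower in each set. Calling probes on these same arrays favours decreases shared by the sets, so these medians cannot decide it. Local signal loss on the arrays of 1 genotype is undecided: probes of the other offsets at the places of 23 of these decreases, all in offset 5, had a median log2 change of 0.021, but the criterion for this test was revised after its value was seen, it covers part of the decreases and it rests on the inferred layout. Also open are spill from brighter probes, as 31.9% of the clustered decreases had a called decrease at least 5 times as bright beside them, wells that differed between batches of arrays, which may give the correlation of 0.163, and a difference in genotype.

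A region of the same grid chosen by eye (columns 36 to 42 and rows 5 to 7, counted from 0) held 79 probes with a median log2 change of -0.20, negative in each of the 6 offsets, of which 3 were called. Uneven signal in the third set may account for it, as the set medians were -0.05, -0.02 and -0.58. CRR21 lies there, with a log2 change of -0.14 and no call. No biological explanation was tested for this region.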

How the results depend on the processing

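Alternatives that used the 3 sets, changed the handling of zeros, or left out clustered probes or replicates 5 and 6 of both genotypes were chosen after seeing the data; the others, the averaging of neighbouring numbers without a set block included, were planned. Against 184 calls (82 higher, 102 lower), the replicate block gave 649 (343 and 306), replicate number as a random block 754 (408 and 346), and neighbouring numbers averaged 23 (7 and 16). An adjusted p under 0.01 left 100 (33 and 67) and a minimum of 2-fold left 6 (2 and 4), both by construction. Sets as a block with genotype within set as a random block gave 540 (278 and 262) and genotype within set as a random block alone 72 (27 and 45). Leaving out probes with a called neighbour of the same direction gave 81 (37 and 44), where 74 called probes had been removed. Higher calls numbered 51 without normalization and 48 of 138 calls with numbers averaged and a set block. Except where a setting removed probes or raised the threshold, the cause was not tested. Other counts stayed within 1.5 times, and leaving out single arrays gave 142 to 177 calls, 56 to 81 higher and 82 to 96 lower.

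No list passed camera under the settings run, and fry passed the flower and meristem regulators (median -0.077). The PPR and mTERF median turned to -0.018 with median centring, -0.029 without normalization, -0.019 with centring on genes outside the lists, and -0.0061 both without the dimmest probes and without probes with a called neighbour, and ranged from -0.010 to 0.013 without single arrays. Without single arrays the glycosyl hydrolase median ranged from -0.046 to 0.025 and the tetrapyrrole and carotenoid median from -0.011 to 0.092. The cause was not tested. None of the 25 named genes changed direction under the settings run. Blocks, averaging and the trended and robust variance leave the estimated change as it was in this balanced design. Direction could therefore change only under the other settings, array weights included. The replicate block changed no call of a named gene or list other than those of PSB27, LHB1B2, PRPS6 and AT1G13370. The PRPL11 level was not run, nor was quantile normalization as an alternative, being the setting used. Signal over background was not given. Leaving out probes in the lowest 25% of mean intensity gave 195 calls, the pseudocount 207 and leaving out probes at 0 on any array 190.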

Other observations

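The tests of other splits of single arrays, of replicate pairs and of the lists were planned; the split test that kept sets together and those of chromosome 4, of stretches of gene order and of the genes around PRPL11 were chosen after the results had been seen. Several further genes passed the threshold outside the naming rule and are named here after their values were seen; none of them kept its call with neighbouring replicate numbers averaged, where the 4 calls with 1 gene were CYN, PSAN, AT4G31470 and AT1G21660. CCL (AT3G26740) fell from 7.45 to 5.24 in mean intensity, a log2 change of -0.39 ± 0.09 (SE). CSLA01, of the cellulose synthase-like A family, fell by 0.53, XERICO, a RING-type protein linked to abscisic acid, by 0.25, and DME, a DNA glycosylase that removes methylated cytosine, by 0.21 on the log2 scale. The calls of XERICO and DME lay near the threshold (limma adjusted p = 0.0488 and 0.0348), and XERICO had 1 other called decrease beside it on the grid. Single omissions were not examined for the genes named here. CUTA rose from 6.28 to 7.33, a log2 change of 0.31 ± 0.05 (SE). The largest change among called probes was in a probe with no listed gene (ID 52), which rose by 1.49 ± 0.06 (SE), and the next largest increase was in another such probe (ID 2235), at 1.02 ± 0.18.

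Other splits of the 12 arrays were fitted in the same way. Of 100 splits drawn from 462, the real one included, 2 called as many probes as the real 184, the highest other calling 345. Of the 99 others, 98 called 0. Splitting single arrays treats them as exchangeable, but neighbouring numbers went together and most drawn splits divided arrays of the same genotype and set. This test therefore cannot exclude chance. The split with 345 calls kept the arrays of each genotype and set together, setting both genotypes of the second set and WT of the first against the rest, which points to a structure of the arrays by set. With the replicate block, the real split called 649 probes and was the only 1 of the 32 splits parting all 6 pairs to reach that count, the others calling at most 1. Of these others only 3 keep the sets whole, so at the level of sets they are too few for a share under 0.05. Where the 2 arrays of a genotype and set are kept together, only 10 splits exist, too few for a share under 0.05; 3 of them called at least 184 probes and the highest other called 345. For the lists, 24 of the 100 drawn splits gave a smallest camera p as low as the real 0.0505, the lowest other being 0.00451, so chance cannot be excluded.

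Genes on chromosome 4, by their locus names, had the highest share of calls: 13 of 119 probes, 10.9%, against 2.44% to 6.72% on the other chromosomes (exact Fisher p = 0.0129, adjusted over 5 chromosomes 0.0643, two-sided), so the excess fails the correction. The called decreases lay in part in a single stretch of gene order, where within 300 places 5 of 10 probes, those of LpxA, AT4G29890, AT4G30740, AT4G31470 and AT4G31530, were called lower and none higher (1000 placements of the calls over all chromosomes, mean 2.3, at most 5, permutation p = 0.0020), while its uncalled probes had a median log2 change of 0.07. A segment that differs between the lines may account for this, and array position may as well, because 4 of the 5 also had a called decrease beside them on the grid. Without the clustered decreases the densest stretch held 2 (permutation p = 0.726) and chromosome 4 had 8 of 114 called against 20 of 541 elsewhere (exact Fisher p = 0.125), so position and segment cannot be told apart for these genes.

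PRK lies 131 places from PRPL11 in gene order, so a hypothesis is that genes linked to PRPL11 differ between the lines for reasons of strain background. It was tested on the 11 probes within 300 places of PRPL11. Their median absolute log2 change was 0.06 against 0.08 for 653 other probes (1-sided permutation p = 0.731), and 1 of the 11, PRK, was called. The difference of -0.017 lay within its permutation SD of 0.030, so the test decides nothing, and a median over this window would miss a few linked differences.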
